A study of Homo sapiens with 24 samples.

How the data were processed

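RNA was measured by poly(A)-selected RNA sequencing in cells derived from H9, an established human embryonic stem cell line. The samples were neural progenitor cells (NPCs) and cerebral organoids grown to day 30. In both systems, libraries carried the label NC, a scrambled short hairpin RNA, or the label of 1 of 2 short hairpin RNAs against KDM2A, sh1 and sh4. There were 5 libraries per group in the NPCs and 3 per group in the organoids. Per the labels' protocols, the hairpins were delivered by lentivirus, transduced cells were selected with puromycin at 1 µg/ml, and libraries were primed with random hexamers. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

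The authors deposited 1 count table per system, unscaled and with a value per gene and library. Per the submitters' processing notes, STAR, featureCounts and the genome build GRCh38.p13 were used, and their versions and settings were not given in the sources used here. The deposited values are expected counts, since 82.4% of the NPC values and 91% of the organoid values were whole and the others carried up to 2 decimals. They were rounded to whole numbers before any test. How fractions arose and whether counting used strand is not given in the sources used here. Reads shared between annotated genes were not tested as the origin, and antisense or overlapping genes could not be told apart.

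The organoid table lists 61544 Ensembl identifiers, of which 40778 had a symbol in the gene table used here. The NPC table lists 10221 gene symbols, and it holds 50.5% of the protein-coding genes of the RefSeq table. In these, edgeR gave an adjusted p under 0.05 between sh1 and NC for 99.7% of the genes and DESeq2 for 99.3%, and the highest unadjusted p in edgeR was 0.127. Between sh4 and NC 88% passed in edgeR, with a highest unadjusted p of 0.999, and between sh1 and sh4 26.8% passed. The listed NPC genes were therefore taken as a set already selected for a difference between sh1 and NC. NPC totals are totals of the listed genes and not library depth, NPC levels in CPM (counts scaled to a common library total) are relative to the counts of listed genes, and scaling assumed that the listed genes had no common shift. Genes outside that table, among them SOX2, FOS, EGR1, VIM, GAPDH and the mitochondrial genes, were not analysed here in the NPCs. Some genes that the rule for named genes picked are not reported here, and list counts include them.

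Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), which kept 9860 NPC genes and 19704 organoid genes, and scaled by TMM. Each system was fitted with its 3 groups together and tested with edgeR's quasi-likelihood test in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method. A gene was called where the adjusted p was under 0.05 and the log2 fold change at least 1 in size, the thresholds of the study's design text. "Rose" and "fell" with both hairpins mean a call in the same direction with sh1 and with sh4. The difference between systems, the mean of the sh1 and sh4 libraries against NC in the NPCs minus the same contrast in the organoids, was fitted over all 6 groups in 10076 genes listed in both tables. Overlaps of calls were tested with two-sided Fisher's exact tests.

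The design, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named KDM2A first. It then took, per system, the 10 genes with the highest and the 10 with the lowest mean log2 fold change among genes called the same way with both hairpins, with a gene symbol and a mean log2 CPM of at least 3. For each single comparison it took the 4 highest and 4 lowest called genes under the same filters. From each list it took up to 4 members with the smallest adjusted p in both hairpins. Genes named outside this rule are said to be chosen after their values were seen.

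The 33 fixed gene lists were H3K36 enzymes and readers, MAPK cascade, MAPK ligands, MAPK feedback, immediate early, neural progenitor, neuron, synapse, forebrain, hindbrain and HOX, choroid plexus, astroglia and oligodendrocyte, neural crest, mesenchyme, muscle, epithelium, endothelium with blood and microglia, mesoderm and endoderm, retina and eye, pluripotency, cell cycle, p53 targets, interferon, hypoxia and glycolysis, unfolded protein and integrated stress response, WNT, Notch, SHH with BMP and TGF-beta, adhesion and matrix, protocadherin, mitochondrially encoded, histone and small RNA genes without poly(A) tails, and cytoplasmic ribosomal protein genes. Each was tested with camera in limma 3.58.1 on the mean effect of both hairpins, with a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. In the NPCs these tests compare a list with other genes of a selected table.

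Both hairpins were compared with the same NC libraries. Their correlation was therefore set beside 20 simulations in which the NC, sh1 and sh4 libraries were drawn from 1 mean per gene, and beside splits of the NC libraries, 20 in the NPCs and 6 in the organoids. Coordinates are from GENCODE 29 on GRCh38. A fold against a group at 0 counts was computed against 3 counts over the group's libraries, and ratios with 1 to 3 counts carry a 95% interval that covers counting error only. Totals per library were 12.7 to 20.2 M counts of listed genes in the NPCs and 15.9 to 18.9 M in the organoids.

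The alternatives were DESeq2 1.42.0, RLE scaling, library size alone, no filter and a stricter one (mean log2 CPM of at least 1), only the groups compared, a replicate block, pooled hairpins, no fold minimum, other list tests, and leaving out each replicate in turn. The procedure was tested on simulated data in which 200 genes per system changed, equally many up and down, besides a shifted list of 20 genes. Among 9840 NPC genes, 99% (sh1) and 96.9% (sh4) of the genes changed by 1.5 on the log2 scale were recovered, and 100% of those changed by 3. Among 19538 organoid genes, 70.2% and 71.3% of the changes of 1.5 and 95.7% of the changes of 3 were recovered. For the difference between systems, 94.4% and 100% were recovered among 9626 genes. At most 3 unchanged genes were called per edgeR comparison within a system and 8 in the difference between systems. Many more genes were called in the real data, so these rates do not test the scaling under broad shifts or the selected NPC table.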

Results

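The data comprised 24 RNA-seq libraries, 15 from NPCs and 9 from day 30 cerebral organoids, which are neural tissue cultures grown from pluripotent cells as aggregates. KDM2A, a demethylase of dimethylated lysine on histone H3K36, was the target of both hairpins, and the series title names this mark and MAPK signalling. NC libraries of the NPCs held 12.7 to 18.2 M counts of the listed genes, and the organoid libraries 15.9 to 18.9 M counts. In the organoids labelled NC, mitochondrial transcripts took 3.07 to 3.5% of the counts and the 10 most abundant genes 5.38 to 5.81%. These shares were 3.14 to 3.29% and 6.73 to 7.41% in the libraries labelled sh1, and 5.05 to 6.02% and 11.8 to 14.4% in those labelled sh4. No replicate pair agreed within sampling noise (chi-square per degree of freedom 2.65 to 33.4 in the NPCs and 5.53 to 55.4 in the organoids), so no library was taken as deposited more than once.

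KDM2A lies on chromosome 11 at 67119269 to 67258087 on the plus strand (GRCh38). In the NPCs its level was 186 ± 15.3 CPM with NC (SD, n = 5, range 163 to 202), 92.0 ± 4.16 CPM with sh1 (n = 5, 89.1 to 98.1) and 95.1 ± 4.19 CPM with sh4 (n = 5, 91.3 to 102). The log2 fold change was -1.02 with sh1 (SE 0.055) and -0.97 with sh4 (SE 0.055), so every knockdown library lay below every NC library and the sh4 change stayed just under the fold threshold (adjusted p = 5.28e-12 and 7.52e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The sh1 value came under the threshold when NC replicate 1 (-0.99) or NC replicate 3 (-0.98) was left out, and the sh4 value passed it without NC replicate 5 (-1.01) and with library size alone (-1.11).

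In the organoids KDM2A was not lower with TMM scaling, while library size alone gave a sh4 log2 fold change of -0.269, short of the fold threshold. Its level was 101 ± 4.14 CPM in the libraries labelled NC (SD, n = 3), 110 ± 7.02 CPM in those labelled sh1 (n = 3) and 101 ± 5.01 CPM in those labelled sh4 (n = 3). The log2 fold changes were 0.14 (95% interval -0.02 to 0.29) and 0.01 (-0.14 to 0.16), with adjusted p = 0.127 and 0.926 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The target gene thus gave no check of the organoid labels, and directions drawn below from the libraries labelled sh1 and sh4 do not rest on a measured KDM2A loss. The contrast of KDM2A differed between the systems by -1.05 on the log2 scale (adjusted p = 1.71e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

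**Figure D1:**
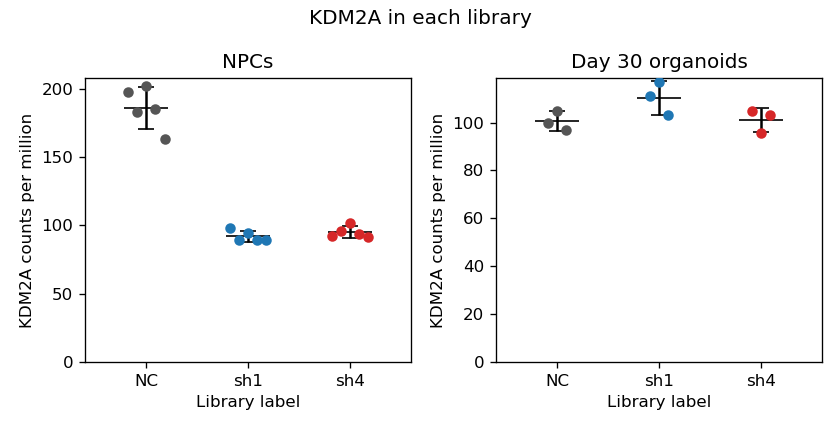
KDM2A in CPM (y axis) for each library by label (x axis), in NPCs (left, CPM of listed genes) and day 30 organoids (right); points are libraries and bars the mean ± SD. In the NPCs sh1 and sh4 libraries sit between 89.1 and 102 and NC libraries between 163 and 202, while the organoid groups overlap between 95.5 and 117.

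The first comparison asked which genes followed both hairpins in the NPCs. SPP1, the secreted matrix protein osteopontin (chromosome 4, 87975650 to 87983426), rose from 26.1 ± 2.15 CPM with NC to 404 ± 52.3 with sh1 and 476 ± 95.7 with sh4 (SD, n = 5 each). NANOG and PRDM14, transcription factors of pluripotent cells, rose from 0.975 ± 0.37 and 1.35 ± 0.61 CPM to 7.30 ± 0.75 and 7.35 ± 0.90 with sh1 and to 21.9 ± 4.13 and 23.1 ± 2.00 with sh4. NPR1, a receptor of natriuretic peptides, rose from 1.24 ± 0.25 to 14.9 ± 1.38 and 12.1 ± 1.82 CPM. IGFN1 (chromosome 1, 201190825 to 201228952) fell from 194 ± 44.5 to 3.31 ± 1.14 and 1.82 ± 0.64 CPM, and KLF4, a transcription factor of pluripotent and epithelial cells, fell from 299 ± 97.1 to 39.0 ± 7.75 and 46.4 ± 4.55 CPM.

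Of 9860 tested genes, 1814 were called with sh1 (619 higher, 1195 lower) and 1784 with sh4 (645 higher, 1139 lower) by edgeR's quasi-likelihood test. With both hairpins 455 genes rose and 838 fell, and 10 were called in opposite directions. The share of higher calls was 34.1% with sh1 and 35.2% for both hairpins, and 23.7% for each with library size alone. That scaling moved the median of all genes by -0.137 with sh1 and -0.143 with sh4 on the log2 scale. The genes that rose with both hairpins by the naming rule also included the metallothioneins MT1E (log2 fold change 3.59 with sh1 and 3.76 with sh4) and MT1X (3.45 and 3.84), the matrix protein TGFBI (2.12 and 4.96), the natriuretic peptide clearance receptor NPR3 (1.99 and 4.45), the WNT ligand WNT8B (3.76 and 2.65) and the calcium-binding protein CALB2 (2.27 and 4.06). Metallothioneins are a family of near-identical genes and NANOG has processed copies with shared reads, so their counts are uncertain.

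Falling with both hairpins were also the glycosyltransferase gene B3GALNT1 (-3.60 with sh1 and -5.61 with sh4), PKHD1L1 (24.7 ± 1.92 CPM with NC, 2.29 ± 0.49 with sh1, 2.50 ± 0.36 with sh4), C21orf62 (-3.09 and -3.35), MBP, a myelin protein (27.0 ± 4.45, 2.95 ± 0.79 and 3.70 ± 0.55 CPM), and CFTR, a chloride channel (-1.38 and -4.58). The zinc finger gene ZNF154 (-1.72 and -4.15), the neuropeptide receptor gene ADCYAP1R1 (-2.58 and -2.94) and VTCN1, an immune checkpoint ligand (-2.90 and -2.59), fell too. Among the named genes of both directions the SE of the log2 fold change was 0.096 (ADCYAP1R1 with sh1) to 0.38 (MT1X with sh1), and the adjusted p was at most 9.73e-08 (MT1X with sh1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Because the listed NPC genes were taken as selected for a difference between sh1 and NC, the counts describe that selection as well as the cells. It bears on the sh1 counts directly and on the sh4 counts through the shared NC libraries.

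Feedback regulators and targets of ERK, a MAPK, were examined next in the NPCs. Of 18 tested MAPK feedback genes 8 rose with both hairpins, 0 fell and 10 did not pass, with median log2 fold changes of 1.12 (sh1) and 0.82 (sh4). The list passed camera (adjusted p = 1.23e-06) but not when the correlation between its genes was estimated (adjusted p = 0.164 with an estimated correlation). DUSP6, an ERK phosphatase (chromosome 12, 89347232 to 89353271), rose from 23.9 ± 0.58 CPM with NC to 101 ± 4.19 with sh1 and 108 ± 13.6 with sh4 (SD, n = 5 each). ETV1, an ETS transcription factor, rose from 26.4 ± 2.00 to 105 ± 6.18 and 120 ± 16.3 CPM. DUSP4 rose from 25.2 ± 1.44 to 95.4 ± 8.59 and 153 ± 17.7 CPM, and SPRY2, an inhibitor of receptor tyrosine kinase signalling, from 33.3 ± 2.71 to 96.1 ± 7.52 and 96.0 ± 8.59 CPM.

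**Figure D2:**
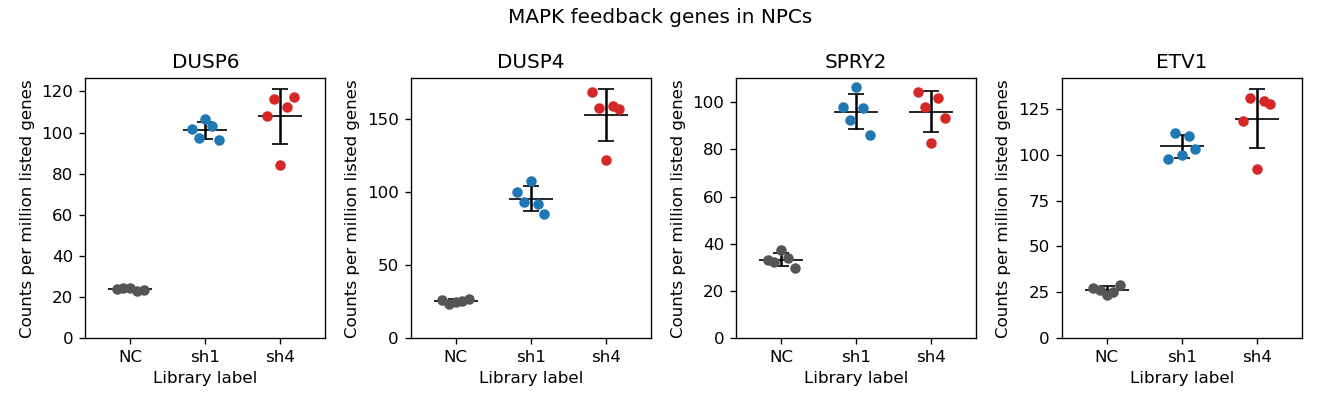
CPM of listed genes (y axis) of DUSP6, DUSP4, SPRY2 and ETV1 in each NPC library by label (x axis); points are libraries and bars the mean ± SD (n = 5 per group). Means rise from 23.9 to 33.3 with NC to 95.4 to 105 with sh1 and 96.0 to 153 with sh4.

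The other MAPK lists did not pass camera. Of 50 tested MAPK cascade genes 2 rose (FGFR4 and INSR) and 4 fell (EGFR, NTRK3, MAPK11 and RPS6KA6), INSR, NTRK3 and MAPK11 being chosen after their values were seen. EGFR, the receptor of epidermal growth factor, changed by -1.16 with sh1 and -1.17 with sh4. That list had positive medians (0.12 and 0.11), a mean of -0.06 and a downward test that was not passed (camera adjusted p = 0.932). Of 22 tested MAPK ligand genes 4 rose (FGF19, NRG1 and, chosen after their values were seen, FGF4 and TGFA) and 2 fell (BTC and GDNF, chosen likewise), with medians of 0.25 and 0.34 (camera adjusted p = 0.567). FGF19 rose by 4.47 and 4.14, and the call of NRG1 with sh4 was lost in 3 fits without 1 library, to 0.92 at the lowest, as well as with DESeq2 and other scalings. FGF19 was near 0 counts in NC 1 and NC 2 (0.0522 and 0.0515 CPM), so its fitted folds depend on the prior count. Among 16 immediate early genes 3 fell, ATF3, MYC and KLF4, and FOSB, chosen after its value was seen, rose, with medians of -0.36 and -0.05 (camera adjusted p = 0.579). MYC fell from 3506 ± 1037 CPM with NC to 550 ± 80.9 with sh1 and 661 ± 101 with sh4 (SD, n = 5 each). ATF3, a stress-induced transcription factor, fell from 159 ± 19.6 to 72.0 ± 5.82 and 74.2 ± 9.57 CPM. In the list of H3K36 enzymes and readers, which holds KDM2A, 0 of 18 tested genes passed with both hairpins (medians -0.01 and 0.05, mean 0, camera adjusted p = 0.875). MSL3 (-0.62 and -0.56), ASH1L (-0.76 and -0.80) and, in the other direction, PHF19 (0.79 and 0.84) stayed under the fold threshold.

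Pluripotency genes rose in the NPCs as a list, and this held with both settings of the list test. Of 16 tested genes 9 rose, POU5F1 fell and 6 did not pass, with medians of 1.59 (sh1) and 1.90 (sh4), camera adjusted p = 3.71e-06 and adjusted p = 0.00494 with an estimated correlation. ZFP42 rose by 3.86 and 3.70, TDGF1, a co-receptor of NODAL, by 2.64 and 3.11, and DPPA3 by 4.26 and 4.28. DPPA3 was near 0 counts with NC (0.0522 CPM in NC 1), so its fitted folds depend on the prior count. POU5F1, chosen after its value was seen, changed by -1.82 and -1.39. Cell cycle genes shifted upward by less: CDC6 (1.58 and 1.37), RRM2 (1.24 and 1.29) and CCNE2, chosen after its value was seen, rose among 34 tested genes and 0 fell (medians 0.66 and 0.56, camera adjusted p = 2.59e-08, adjusted p = 0.21 with an estimated correlation). PCNA (0.89 and 0.67) stayed under the fold threshold.

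The lists of neural stages and regions gave different results in the NPCs. Of 21 tested neural progenitor genes 5 rose and 0 fell (medians 0.53 and 0.29, camera adjusted p = 0.102), among them FABP7, a radial glial fatty acid binding protein (2.31 and 2.28), SOX1 (1.36 and 1.95), PTPRZ1 (1.43 and 1.98) and SLC1A3 (1.45 and 1.51), with PROM1 chosen after its value was seen. Neuron genes had 0 of 23 higher and 2 lower, NEUROG1 (-2.58 and -1.79) and MAPT, the tau gene (-1.39 and -1.26), with medians of -1.06 and -0.39 (camera adjusted p = 0.0227, adjusted p = 0.224 with an estimated correlation). Of 25 synapse genes 1 rose (SYN3, chosen after its value was seen) and 7 fell, such as the glutamate receptor gene GRIN2A (-2.64 and -2.14) (medians -0.66 and -0.33, camera adjusted p = 0.181). Of 9 forebrain genes 1 fell and 0 rose, and the medians had opposite signs with the hairpins, 0.97 with sh1 and -0.83 with sh4 (camera adjusted p = 0.567). Of 5 hindbrain and HOX genes 4 rose, HOXB1 (1.60 and 1.77), HOXA2 (2.84 and 2.77), GBX2 (1.21 and 2.08) and, chosen after its value was seen, PAX5 (medians 1.60 and 2.03, camera adjusted p = 0.0227, adjusted p = 0.164 with an estimated correlation). HOXA2 started from a low level (0.209 CPM in NC 1).

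Markers of other cell types were also tested in the NPCs. Of 19 mesenchyme genes 5 rose and 0 fell, among them LUM, a matrix proteoglycan (1.47 and 3.67), and THY1 (1.29 and 1.93), with BGN, FOXC2 and MFAP5 chosen after their values were seen (medians 0.61 and 1.24, camera adjusted p = 6.85e-06, adjusted p = 0.164 with an estimated correlation). Of 8 neural crest genes 1 rose and 0 fell (medians 0.73 and 0.78, camera adjusted p = 0.0227, adjusted p = 0.18 with an estimated correlation). Retina and eye genes had 0 of 7 higher and 3 lower, the melanin pigment genes TYR (-5.44 and -4.72), DCT (-1.28 and -2.67) and PMEL (-1.05 and -2.02, the sh1 call lost without 1 library) (medians -1.06 and -2.02, camera adjusted p = 0.0139, adjusted p = 0.18 with an estimated correlation). Among 12 astroglia and oligodendrocyte genes 2 rose, among them MOG, chosen after its value was seen, and 5 fell, MBP, S100B (-2.35 and -2.74), SPARCL1 and, chosen likewise, GFAP and AGT, with the sh1 call of SPARCL1 lost in 3 fits without 1 library (medians -0.91 and -0.35, camera adjusted p = 0.397). For choroid plexus, 2 of 17 rose, WNT8B and, chosen after its value was seen, CLIC6, and 1 fell, RSPO1, chosen likewise (medians -0.40 and -0.52, camera adjusted p = 0.887). Muscle had ACTA1 higher (1.58 and 1.61) and MYH7 lower (-1.92 and -2.10) of 8 (medians 0.51 and 0.33, camera adjusted p = 0.875).

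Epithelium genes showed 3 lower of 15, the tight junction genes CLDN3 (-1.94 and -2.14) and CLDN4 (-1.02 and -1.02, calls lost in 4 fits for sh1 and 5 for sh4 without 1 library) and the transcription factor gene ELF3, with medians of opposite sign, 0.49 and -0.45 (camera adjusted p = 0.71). Of 10 endothelium, blood and microglia genes the VEGF receptor gene KDR rose (2.93 and 3.25) and CDH5 and VWF fell (medians 0.68 and -0.35, camera adjusted p = 0.681). Of 3 mesoderm and endoderm genes APOB and MESP1 fell (medians -1.30 and -1.51, camera adjusted p = 0.336).

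Interferon response genes fell in the NPCs, 11 of 32 with both hairpins and 0 higher (medians -1.08 and -0.54, camera adjusted p = 3.71e-06, adjusted p = 0.35 with an estimated correlation). IFIT2, an interferon-induced RNA-binding protein, fell from 959 ± 238 CPM with NC to 176 ± 26.5 with sh1 and 153 ± 20.6 with sh4, and IRF7, a transcription factor of the response, from 15.0 ± 1.67 to 2.88 ± 0.57 and 4.69 ± 0.29 CPM (SD, n = 5 each). The RNA sensor gene RIGI changed by -1.25 and -1.28. Hypoxia and glycolysis genes had small positive medians (0.36 and 0.37), with 0 of 20 past the fold threshold with both hairpins (camera adjusted p = 0.0134, adjusted p = 0.223 with an estimated correlation). ENO1, a glycolytic enzyme gene, had log2 fold changes of 0.86 and 0.89. In the unfolded protein and integrated stress response list PPP1R15A (-2.10 and -1.89), DDIT3 (-2.22 and -1.56) and ATF3 fell among 22 genes (medians -0.28 and -0.18, camera adjusted p = 0.336).

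For p53 targets, BBC3 fell (-1.21 and -1.12) among 15 genes (medians 0.27 and 0.11, camera adjusted p = 0.737). Of 26 WNT genes 4 rose, WNT8B, the secreted antagonists SFRP1 (1.99 and 1.35) and SFRP2 (2.15 and 1.62) and, chosen after its value was seen, FZD8, and WNT10B fell, with medians of 0.25 and -0.16, a mean of -0.04 and an upward test (camera adjusted p = 0.579). Notch had JAG2 lower (-1.04 and -1.24, the sh1 call lost without 1 library) of 15 (medians -0.79 and -0.21, camera adjusted p = 0.277). SHH, BMP and TGF-beta genes had 5 higher of 27, among them the antagonists GREM1 (2.21 and 2.11) and FST (1.86 and 1.84) and, chosen after their values were seen, TGFB1 and INHBA, and 2 lower, HHIP and, chosen likewise, BMP6 (medians 0.10 and 0.05, camera adjusted p = 0.713). Adhesion and matrix genes had CDH4 higher and CNTN1 and RELN lower of 27, CDH4 and RELN being chosen after their values were seen (medians 0.31 and 0.12, camera adjusted p = 0.33). Protocadherins had 0 of 20 past the threshold with both hairpins (medians -0.38 and -0.53, camera adjusted p = 0.277).

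Among 5 histone and small RNA genes 1 fell, and H1-5, chosen after its value was seen, rose (medians -1.36 and -0.92, camera adjusted p = 0.0721). Ribosomal protein genes had 0 of 15 past the threshold, with medians of 0.09 and -0.06 (camera adjusted p = 0.875). Mitochondrially encoded genes were not analysed here in the NPCs. In each NPC list the numbers that rose and fell adjusted over the list alone equalled those over all genes. Pluripotency was the 1 list of 10 passing camera that held with an estimated correlation.

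The hairpins also differed from each other in the NPCs. ZNF512 (chromosome 2, 27582969 to 27623215) was lower with sh4 (log2 fold change of sh1 over sh4 4.38), as were LMX1A, a roof plate transcription factor (22.4 ± 2.13 CPM with sh1, 1.16 ± 0.23 with sh4, 7.60 ± 1.36 with NC), and WNT1 (12.1 ± 2.51, 1.12 ± 0.086 and 16.7 ± 2.82 CPM). CFTR was lower with sh4 as well (3.21). IGF2, a growth factor of the insulin family, was higher with sh4 (63.6 ± 4.02 CPM, against 7.23 ± 1.84 with sh1 and 23.7 ± 1.86 with NC), as were LEFTY2, an inhibitor of NODAL (89.4 ± 37.6, 12.4 ± 1.18 and 3.95 ± 0.61 CPM), TGFBI (-2.84) and DCN (-2.80). Of 9860 genes 456 were called between the hairpins, 215 higher with sh1 and 241 higher with sh4, and KDM2A itself did not differ detectably between them (-0.05, adjusted p = 0.582, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

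The same comparison was made between the organoid libraries labelled sh1 or sh4 and those labelled NC. GAD2, an enzyme of GABA synthesis, fell from 31.8 ± 4.83 CPM with the label NC to 0.128 ± 0.032 with sh1 and 0.147 ± 0.16 with sh4, and POU5F1, a pluripotency factor, from 231 ± 67.0 to 0.475 ± 0.51 and 0.680 ± 0.54 CPM. ALB, serum albumin (chromosome 4, 73397114 to 73421412), rose from 0.221 ± 0.16 to 738 ± 371 and 3998 ± 2942 CPM (SD, n = 3 each).

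Of 19704 tested genes 3980 were called between the labels sh1 and NC (2334 higher, 1646 lower) and 7057 between sh4 and NC (3967 higher, 3090 lower) by edgeR's quasi-likelihood test. With both labels 1923 rose and 1303 fell, and 44 went in opposite directions. For sh4 the share of higher calls was 56.2%, and 43.1% with library size alone, a scaling that moved the median of all genes by -0.274 on the log2 scale. A further 4 genes that rose were at 0 counts in every NC library. APOH, a plasma apolipoprotein, was at least 182-fold (sh1) and 1380-fold (sh4) higher, SERPINA7, a thyroid hormone carrier, at least 141-fold and 724-fold, AGR2, a protein of secretory epithelium, at least 113-fold and 419-fold, and the complement gene C1QC at least 85.8-fold and 385-fold.

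Others that rose with both labels by the naming rule were the glucuronosyltransferase gene UGT2B10, whose NC libraries held 1 count in all (ratio 441, 95% interval 78.7 to 17400, for sh1 and 3120, 560 to 123000, for sh4), and CFI, complement factor I (ratio 430, 119 to 3560, and 1840, 510 to 15200). APOC2, an apolipoprotein (403, 111 to 3330, and 1590, 439 to 13100), TM4SF4 (468, 83.6 to 18500, and 1130, 203 to 44800) and ITIH2, a plasma protein (log2 fold change 7.78 and 9.95), rose likewise. The genes that fell included DLX6-AS1 (-9.16 and -7.53), an antisense transcript at the DLX5 and DLX6 locus whose reads could not be told from the opposite strand, and the nicotinamide riboside kinase gene NMRK2 (-8.27 and -8.24). The stem cell RNA genes ESRG (-8.23 and -7.34) and MIR302CHG (-6.41 and -6.33), the alkaline phosphatase gene ALPG (-8.23 and -6.76), which has close paralogs, and SLC32A1, the vesicular GABA transporter (-6.34 and -5.67), fell too. GSX2, a homeobox gene of the ventral telencephalon, fell from 35.6 ± 2.97 CPM to 1.17 ± 0.89 with sh1 and to 1 count over 3 libraries with sh4 (ratio 1750, 313 to 69100). Among the genes of this paragraph and C1QC the adjusted p was at most 0.00794 (C1QC with sh1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

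Neural lists were lower in the organoid libraries labelled sh1 and sh4 by camera with the preset correlation, none of them with an estimated correlation. Of 30 neural progenitor genes 15 fell and 0 rose, such as the transcription factor genes NR2E1 (-4.65 with sh1 and -5.75 with sh4), SOX1 (-2.64 and -4.30) and SOX3 (-3.04 and -4.43). The list medians were -1.04 and -1.94 (camera adjusted p = 8.16e-14, adjusted p = 0.115 with an estimated correlation). Of 34 neuron genes 10 fell (9 adjusted over the list alone) and 0 rose, such as the neurogenic factor gene NEUROG2 (-2.62 and -6.19) and MYT1L (-2.03 and -4.77). Medians of this list were -0.66 and -2.38 (camera adjusted p = 8.29e-06, adjusted p = 0.474 with an estimated correlation). Of 47 synapse genes 22 fell, such as GAD1 (-5.15 and -4.98) and the glutamate receptor gene GRIN2B (-4.74 and -5.43), and GRIN2A, chosen after its value was seen, rose. Medians over the list were -0.85 and -2.32 (camera adjusted p = 2.5e-20, adjusted p = 0.101 with an estimated correlation). Of 22 forebrain genes 11 fell, such as DLX5 (-5.11 and -3.53) and DLX2 (-3.13 and -4.97), and BARHL2, chosen after its value was seen, rose. The medians for sh1 and sh4 were -0.88 and -2.77 (camera adjusted p = 3.42e-11, adjusted p = 0.0937 with an estimated correlation). The libraries labelled sh4, with the lower medians, were also those with a mitochondrial share of 5.05 to 6.02%.

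Lists of other regions and tissues were tested next in the organoids. Of 23 choroid plexus genes 18 rose and 0 fell, such as the serotonin receptor gene HTR2C (5.70 ± 0.89 CPM with NC, 52.4 ± 8.48 with sh1, 96.0 ± 35.3 with sh4), TRPM3 (3.54 and 4.25) and LMX1A (3.84 and 3.15). Median changes were 2.26 and 2.32 (camera adjusted p = 4.71e-08, adjusted p = 0.249 with an estimated correlation). Of 29 mesenchyme genes 18 rose and 0 fell, such as the collagen gene COL1A1 (661 ± 146, 3594 ± 177 and 6345 ± 627 CPM), the matrix gene POSTN (3.07 and 3.56) and BGN (2.08 and 1.96). Over the list the medians were 1.86 and 2.31 (camera adjusted p = 3.98e-18, adjusted p = 0.0937 with an estimated correlation). Of 35 hindbrain and HOX genes 17 rose (18 adjusted over the list alone), such as HOXC6 (3.75 and 4.05), HOXB3 (1.93 and 1.54) and HOXB7 (3.01 and 3.95), and GBX2, chosen after its value was seen, fell. The list medians were 2.15 and 1.93 (camera adjusted p = 5.31e-05, adjusted p = 0.462 with an estimated correlation). Of 19 endothelium, blood and microglia genes 10 rose, such as CLDN5 (2.58 and 2.30) and AIF1, a microglial and macrophage gene (2.83 and 4.29), and HBE1, chosen after its value was seen, fell. Medians of this list were 1.58 and 2.23 (camera adjusted p = 0.006, adjusted p = 0.474 with an estimated correlation). In these libraries the 10 most abundant genes took 6.73 to 7.41% (sh1) and 11.8 to 14.4% (sh4) of the counts, against 5.38 to 5.81% with NC.

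Of 15 astroglia and oligodendrocyte genes 5 rose, SPARCL1 (4.91 and 4.39), S100B (5.50 and 2.46), the growth factor receptor gene PDGFRA (2.37 and 1.60), CSPG4 and, chosen after its value was seen, AGT, and OLIG2, chosen likewise, fell. Medians over the list were 0.75 and 1.29 (camera adjusted p = 0.00738, adjusted p = 0.101 with an estimated correlation). Neural crest had SNAI2 (1.79 and 1.85), TWIST1 (4.30 and 3.19) and, chosen after its value was seen, PRDM1 higher and 0 lower of 20, with medians of opposite sign, 0.94 and -0.17 (camera adjusted p = 0.248). Of 14 muscle genes 4 rose, DES (2.38 and 3.41), TNNI1, TNNT2 and, chosen after its value was seen, TNNT3, and 2 fell, ACTC1 (-2.38 and -3.38) and, chosen likewise, ACTA1 (medians of opposite sign, -0.11 and 0.82, camera adjusted p = 0.128). Epithelium had 0 of 20 past the threshold in 1 direction with both labels, and the keratin genes KRT18 (-0.43 and 1.62) and KRT8 (-0.28 and 1.55) had opposite signs. The medians for sh1 and sh4 were -0.56 and 1.45 (camera adjusted p = 0.453). Of 22 mesoderm and endoderm genes 10 rose (11 adjusted over the list alone), such as ALB, GATA6 (1.95 and 1.61) and HAND2 (2.19 and 2.52), and 6 fell, such as MIXL1 (-3.50 and -3.12). Median changes were 0.88 and 1.44 (camera adjusted p = 0.126). Of 10 retina and eye genes MITF (1.62 and 2.29) and MLANA (ratio 119, 95% interval 40.4 to 580, and 24.5, 8.04 to 122) rose and PAX6 (-3.56 and -4.41) and LHX2 (-2.57 and -5.32) fell. Over the list the medians were -0.33 and -0.96 (camera adjusted p = 0.501).

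Pluripotency genes fell in 16 of 18 tested cases and 0 rose in the organoids. The NC libraries at day 30 held these transcripts, such as LIN28A at 240 CPM. A high level in that NC set cannot be told apart from a fall in the sets labelled sh1 and sh4. The list medians were -3.30 and -3.20 (camera adjusted p = 3.55e-17, adjusted p = 0.101 with an estimated correlation). LIN28A, an RNA-binding protein of stem cells, fell from 240 ± 22.2 CPM to 6.24 ± 0.58 and 10.7 ± 4.29 (SD, n = 3 each), and NANOG fell to 1 count with sh1 (ratio 874, 95% interval 157 to 34600) and 2 counts with sh4 (392, 108 to 3250). Of 36 cell cycle genes PLK1, a mitotic kinase gene, fell (-1.04 and -1.33, the sh1 call lost in 3 fits without 1 library) and 0 rose. Medians of this list were -0.26 and -0.59 (camera adjusted p = 0.00323, adjusted p = 0.694 with an estimated correlation). Of 25 p53 targets 6 fell, such as GDF15 (-2.17 and -1.66) and PMAIP1 (-2.49 and -2.84), and TP53I3 and CDKN2B, chosen after their values were seen, rose. Medians over the list were -0.77 and -0.39 (camera adjusted p = 8.91e-06, adjusted p = 0.0937 with an estimated correlation). Of 33 interferon genes 14 rose and 0 fell, such as the RNA sensor gene IFIH1 (3.86 and 4.47) and IFIT3 (2.79 and 3.81). The medians for sh1 and sh4 were 0.85 and 1.85 (camera adjusted p = 8.29e-06, adjusted p = 0.356 with an estimated correlation).

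Of 25 MAPK feedback genes 5 fell in the organoids, EPHA4 (-1.58 and -2.45) and, chosen after their values were seen, DUSP8, SPRY4, SPRED3 and ETV4, and DUSP9, chosen likewise, rose. Median changes were -0.65 and -0.70 (camera adjusted p = 0.00259, adjusted p = 0.101 with an estimated correlation). Of 70 MAPK cascade genes 3 rose, the receptor genes PDGFRB (2.59 and 2.18), PDGFRA and, chosen after its value was seen, EGFR, and 2 fell, RASGRF1 (-3.53 and -2.57) and, chosen likewise, RASGRP1, with medians of -0.01 and -0.03, a mean of 0.06 and a downward test (camera adjusted p = 0.916). Of 39 MAPK ligand genes 13 rose, such as PDGFC (2.03 and 1.76), and 6 fell, such as FGF2 (-1.72 and -2.10) and FGF19 (-4.76 and -3.56). Over the list the medians were 0.03 and 0.07 (camera adjusted p = 0.92). Of 27 immediate early genes 5 fell, ATF3 (-1.45 and -1.40), the nuclear receptor gene NR4A1, FOSL1 and, chosen after their values were seen, IER5 and ARC, and 0 rose. The list medians were -0.36 and -0.37 (camera adjusted p = 0.15). Among 25 H3K36 enzymes and readers SMYD2 rose (1.17 and 1.23, the sh4 call lost with library size alone) and the DNA methyltransferase gene DNMT3B, held by the pluripotency list too, fell (-2.73 and -2.90). Medians of this list were -0.11 and -0.29 (camera adjusted p = 0.0838).

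Of 42 WNT genes 5 rose, the antagonist gene DKK2 (6.45 and 6.66) and, chosen after their values were seen, WNT2B, WNT3A, WNT10B and WIF1, and 5 fell, WNT7A (-4.23 and -5.24), FZD8 and, chosen likewise, FZD3, FZD5 and SP5. Medians over the list were 0.32 and 0.24 (camera adjusted p = 0.801). Notch genes had 7 of 25 lower, such as the target genes HES5 (-3.02 and -5.65) and NRARP (-1.54 and -2.13), and 2 higher, MAML2 and, chosen after its value was seen, HEYL. The medians for sh1 and sh4 were -0.22 and -0.89 (camera adjusted p = 0.00159, adjusted p = 0.356 with an estimated correlation). SHH, BMP and TGF-beta genes had 7 of 39 higher, such as TGFB3 (3.07 and 3.73), and 2 lower, ID4 (-1.58 and -2.54) and, chosen after its value was seen, BMP6. Median changes were 0.36 and 0.65 (camera adjusted p = 0.0604). Of 40 adhesion and matrix genes 6 rose, such as the integrin gene ITGA1 (4.14 and 3.92), and 6 fell, such as the matrix gene TNR. Over the list the medians were 0.45 and 0.23 (camera adjusted p = 0.153). Of 38 protocadherins PCDHAC2 (1.82 and 3.26) and PCDH7 rose and 4 fell, PCDH11X and, chosen after their values were seen, PCDHAC1, PCDHB3 and PCDHGC4. The list medians were -0.11 and -0.77 (camera adjusted p = 0.214).

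Hypoxia and glycolysis genes had CA9 and NDRG1, chosen after their values were seen, higher and ENO2, a neuronal enolase (-1.16 and -2.42), lower of 30. Medians of this list were -0.20 and -0.47 (camera adjusted p = 0.0604). Among 28 unfolded protein and integrated stress response genes ATF3 and, chosen after its value was seen, CHAC1 fell and 0 rose. Medians over the list were -0.34 and -0.19 (camera adjusted p = 0.006, adjusted p = 0.523 with an estimated correlation). Among 15 mitochondrially encoded genes 0 passed the threshold with both labels. The medians for sh1 and sh4 were 0.20 and 1.33 (camera adjusted p = 0.00075, adjusted p = 0.474 with an estimated correlation). MT-ND2, a subunit of respiratory complex I, had log2 fold changes of 0.42 and 1.68, and MT-CYB of 0.54 and 1.41. Histone and small RNA genes had 4 of 17 lower, RN7SK (-2.74 and -3.53), RN7SL1, RN7SL2 and H4C5, whose sh4 call was lost without NC 2 and sh4 1. Median changes were -0.20 and -0.78 (camera adjusted p = 0.113). The list holds RNAs without poly(A) tails and the libraries were poly(A)-selected. In both systems its levels can therefore reflect library preparation as well as expression, which was not tested. Of 70 ribosomal protein genes 0 passed. Over the list the medians were 0.01 and 0.17 (camera adjusted p = 0.314). Elsewhere in the organoid lists the counts adjusted over the list alone equalled those over all genes.

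**Figure D3:**
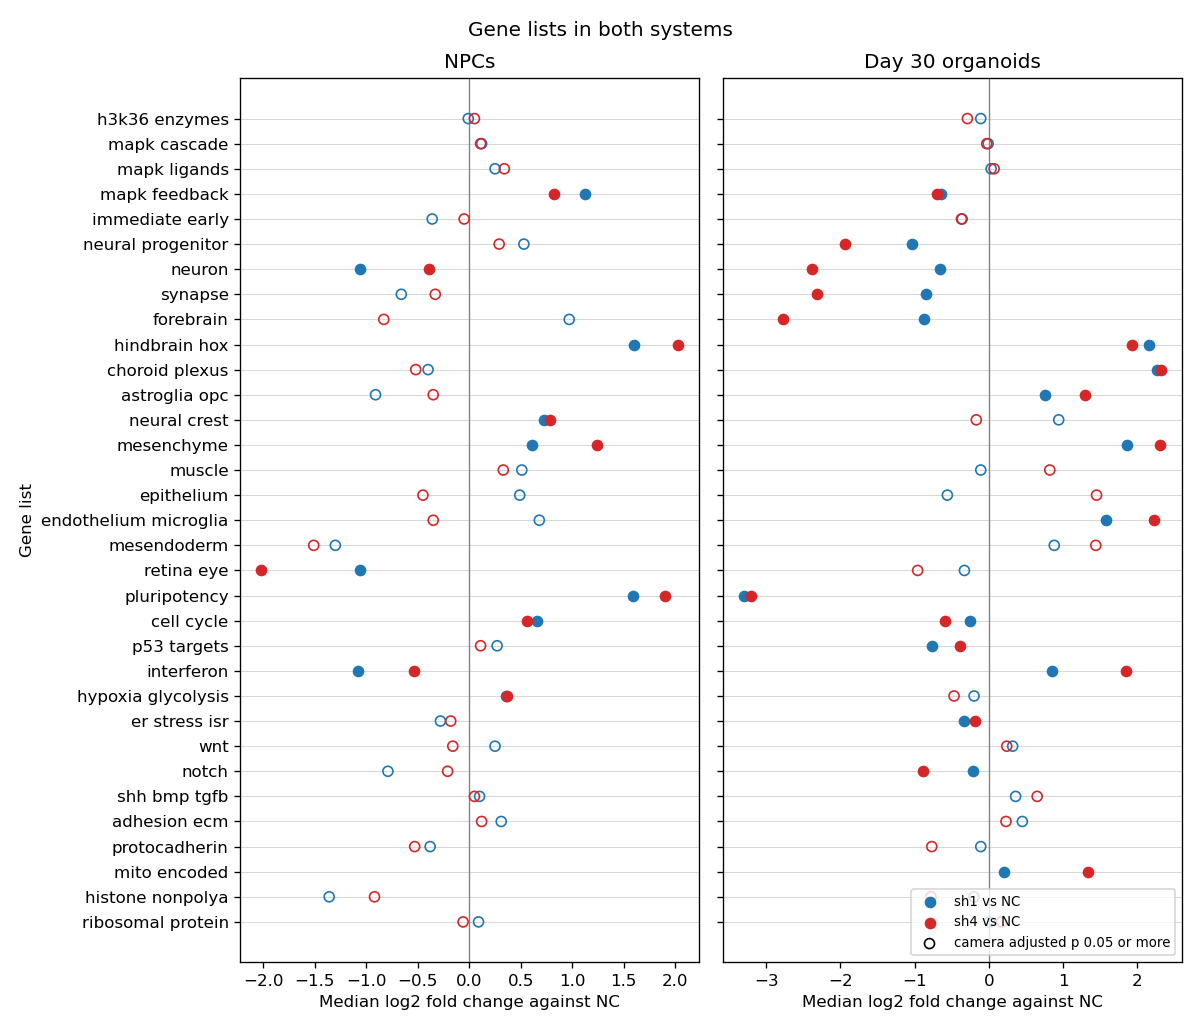
Median log2 fold change against NC (x axis) of each gene list (y axis) in NPCs (left) and day 30 organoids (right), with 1 point per hairpin label and filled points where camera with the preset correlation gave an adjusted p under 0.05. Pluripotency medians lie at 1.59 and 1.90 in the NPCs and at -3.30 and -3.20 in the organoids.

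The organoid libraries labelled sh1 and sh4 were also compared with each other. TRIM67 (61.7 ± 25.6 CPM with sh1, 2.41 ± 0.82 with sh4), SKOR2, a transcriptional corepressor gene (22.9 ± 2.92 and 0.913 ± 0.83), ISLR2 (63.7 ± 11.8 and 3.62 ± 1.47) and GSX2 were higher with the label sh1 (SD, n = 3 each). SLN, a regulator of the muscle calcium pump (0.530 ± 0.27 and 35.4 ± 13.7 CPM), CRHBP (0.384 ± 0.20 and 14.4 ± 9.38), the complement gene C4B, a near copy of C4A (1.99 ± 0.30 and 64.1 ± 7.71), and the GABA receptor gene GABRP (13.6 ± 21.2 and 362 ± 67.9, with no adjusted p from DESeq2) were higher with the label sh4. For GABRP the sh1 libraries were at 38.1, 0.714 and 1.86 CPM, and the log2 fold change of -4.74 was -8.12 without the first of them. Of 19704 genes 3841 were called by edgeR's quasi-likelihood test, 1562 higher with sh1 and 2279 higher with sh4. The share higher with sh1 was 40.7%, and 57% with library size alone, which moved the median of all genes by 0.23 on the log2 scale.

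Fold changes with the hairpins went together across genes in both systems, and both were taken against the same NC libraries. In the NPCs SPP1, DUSP6 and MYC lay on the shared axis and ZNF512 and IGF2 off it. Pearson's correlation across 9860 NPC genes, which are not independent replicates, was 0.864, against 0.503 in simulated unchanged groups, and the covariance was 0.71 against 0.00806, a difference of 0.702. With the NC libraries split between the hairpins the median correlation was 0.847 (0.826 to 0.854 over 20 splits). The simulation did not include the selection of the listed NPC genes for a difference between sh1 and NC, so the excess over it contains that selection. In the organoids the correlation across 19704 genes was 0.842 against 0.489 simulated, and the covariance 2.13 against 0.08, a difference of 2.05. With the 3 NC libraries there split between the hairpins, which was added after the result was seen, the median correlation was 0.777 (0.761 to 0.790 over 6 splits). In both systems the parts came from the same NC set. The splits therefore remove only the noise of shared libraries, and a difference of the whole NC set from the others stays in both parts.

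**Figure D4:**
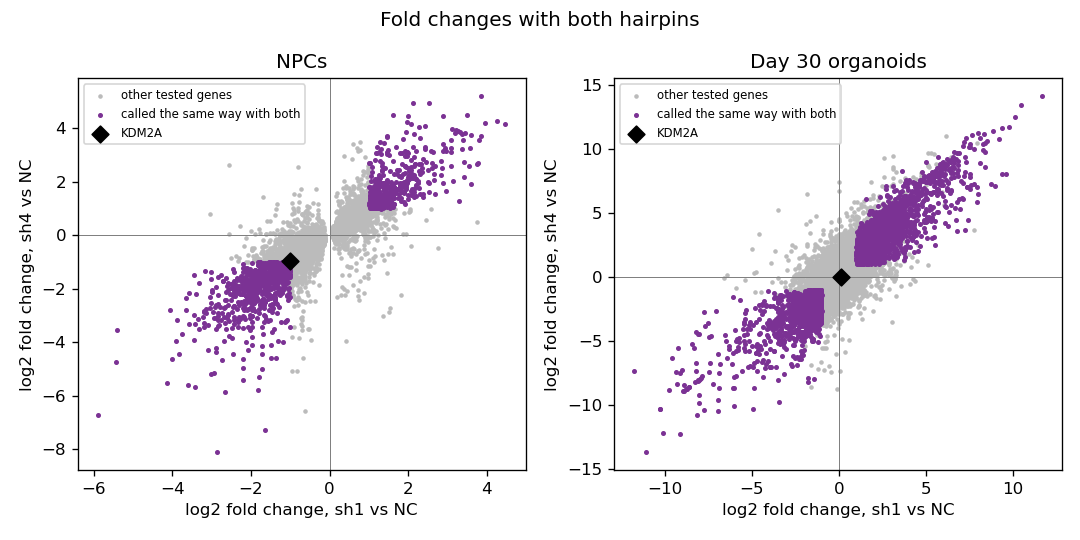
Log2 fold change of sh4 against NC (y axis) by that of sh1 against NC (x axis) for each tested gene in NPCs (left) and day 30 organoids (right); purple points were called the same way with both hairpins, grey points are the other genes and the diamond is KDM2A. KDM2A sits at -1.02 and -0.97 in the NPCs and near the origin in the organoids.

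The last comparison asked whether the contrast of the libraries labelled sh1 and sh4 with those labelled NC differed between NPCs and organoids. NANOG and PRDM14 rose in the NPCs and fell in the organoids, and APOB, a lipoprotein gene, and IGFN1 fell in the NPCs and rose in the organoids, the organoid sh4 call of IGFN1 being lost in 4 fits without 1 library and with library size alone. As a list, pluripotency genes had a median log2 change of 2.40 in the NPCs and -2.53 in the organoids among 18 genes in both tables (camera adjusted p of the difference = 1.89e-18, adjusted p = 0.00556 with an estimated correlation). The NPC fit alone had kept 16 of the list, with medians of 1.59 (sh1) and 1.90 (sh4). The organoid side of this difference rests on pluripotency transcripts present in the NC set, which may itself stand apart. The MAPK feedback list had a median of 1.04 in the NPCs and -0.71 in the organoids (camera adjusted p of the difference = 1.76e-06, adjusted p = 0.0571 with an estimated correlation). Of 10076 genes 3440 were called for the difference by edgeR's quasi-likelihood test, 1365 with the NPC contrast above the organoid contrast and 2075 below it.

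Among 9626 genes tested in both systems, 77 rose and 63 fell in both, against 34.7 and 35.9 for independent lists (odds ratio 2.66, adjusted p = 1.43e-11, and 1.96, adjusted p = 9.88e-06, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 4 overlaps). Opposite calls were more frequent, with 82 genes higher in the NPCs and lower in the organoids against 19.6 (odds ratio 5.83, adjusted p = 7.7e-30) and 184 lower in the NPCs and higher in the organoids against 63.3 (odds ratio 4.26, adjusted p = 5.32e-44, the same Fisher's exact tests). NANOG and PRDM14 are among the former and APOB and IGFN1 among the latter. All 4 overlaps exceeded independence, so genes called in either system were called more often in the other whatever the direction. The excess in the same direction thus shows no shared response by itself. Genes are not independent and the NPC genes were taken as selected on sh1 against NC, for which these p-values do not allow. As KDM2A was not lower with TMM scaling in the organoid libraries labelled sh1 and sh4, the systems differ in the target gene as well as in the cells.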

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

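The tests of precision, of exchanged labels, of a single library, of other cell types and of organoid sets, and leaving out abundant genes or NC 2 with sh4 1, were chosen after the result was seen. Several results stood out because the contrast of sh1 and sh4 with NC differed between NPCs and organoids. For NANOG the contrast in the NPCs minus that in the organoids was 12.60 on the log2 scale (3.68 and -8.92, adjusted p = 5.43e-18), for PRDM14 11.80 (3.27 and -8.54, adjusted p = 3.82e-16), for GALP, a neuropeptide gene, 8.90 (3.09 and -5.81, adjusted p = 1.86e-09) and for VRTN 8.55 (1.34 and -7.21, adjusted p = 2.8e-16), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For IGFN1 it was -9.15 (-6.30 and 2.85, adjusted p = 1.85e-12), for TTR, a choroid plexus and liver gene, -8.47 (-2.19 and 6.29, adjusted p = 0.0252) and for APOB -8.41 (-3.68 and 4.74, adjusted p = 2.33e-07), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fitted differences of genes near 0 counts, NANOG, PRDM14, GALP and VRTN in organoids and APOB and TTR in NPCs, depend on the prior count and bound no fold, and the TTR call was lost in 3 fits without 1 library. In all 3440 genes differed between the systems.

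By list, the difference between systems was 4.79 for pluripotency (2.40 in the NPCs and -2.53 in the organoids, camera adjusted p = 1.89e-18, adjusted p = 0.00556 with an estimated correlation). No other list kept it with an estimated correlation. The organoid side of the pluripotency difference rests on transcripts present in the NC set. The MAPK feedback list differed by 1.72 (1.04 and -0.71, camera adjusted p = 1.76e-06, adjusted p = 0.0571 with an estimated correlation), neural progenitor genes by 1.30 (0.03 and -1.42, 7.41e-08, adjusted p = 0.104 with an estimated correlation) and synapse genes by 1.09 (-0.40 and -1.57, 0.00116, adjusted p = 0.408 with an estimated correlation). Cell cycle genes differed by 1.06 (0.61 and -0.45, 7.29e-08, adjusted p = 0.473 with an estimated correlation) and hypoxia and glycolysis genes by 0.81 (0.27 and -0.37, 0.00543, adjusted p = 0.693 with an estimated correlation). Choroid plexus genes differed by -2.80 (-0.60 and 2.49, 0.000156, adjusted p = 0.298 with an estimated correlation), interferon genes by -2.02 (-0.89 and 1.42, 2.19e-07, adjusted p = 0.298 with an estimated correlation), astroglia and oligodendrocyte genes by -1.10 (-0.33 and 0.66, 0.00974, adjusted p = 0.0627 with an estimated correlation) and mesenchyme genes by -0.92 (0.98 and 2.04, 0.00511, adjusted p = 0.298 with an estimated correlation).

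A library lay far from the others of its group in 3 of 69 groups of values, where chance gives about 1 in 20 (gap over range above 0.71). NPC library NC 3 had 12.7 M counts of listed genes, the others of its group 16.9 to 18.2 M. In NPC library sh4 3 the ERK phosphatase gene DUSP6 was at 84.5 CPM (others 108 to 117) and DUSP4 at 122 CPM (others 157 to 168).

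KDM2A differed between systems by -1.05 (-0.98 in the NPCs and 0.07 in the organoids, adjusted p = 1.71e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Too little precision was argued against by the lower 95% bounds in the organoids, of which the lower was -0.14. Labels exchanged among the 9 organoid libraries would leave some libraries low, but the lowest KDM2A level was 0.816 of the highest (95.5 and 117 CPM). Scaling moved by abundant genes was argued against by a sh4 log2 change of 0.018 (SE 0.068) without 51 mitochondrial and abundant genes, again with TMM. With library size alone the sh4 change was -0.269 (adjusted p = 0.00844, the same test). Scaling thus sets whether a small fall is seen with sh4, but not one as large as in the NPCs (-0.97). Silenced hairpins, outgrowth of cells without them and wrong labels of whole sets stay open and were not tested, as does a difference between the cell systems.

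In the organoids labelled sh1 and sh4 choroid plexus and mesenchyme genes were higher and forebrain genes lower, and 6 of the 6 libraries lay beyond every NC library in each of these lists, against a single odd library. With TMM the forebrain median was -2.11 with and without the abundant genes, so leaving them out was no test of counts taken up by them. Library size alone, which does not adjust for such genes, moved the median of all genes by -0.044 (sh1) and -0.274 (sh4). Forebrain medians were -0.88 and -2.77, and these larger changes argue against counts taken up by abundant genes as the source. A lower share of neural cells that raises every other cell type alike was examined with lists picked after their values were seen. For sh1 the choroid plexus (2.26, 23 genes) and epithelium (-0.56, 20 genes) medians differed by 2.82 (permutation p = 1e-05, the smallest that 100000 resamples of genes can give, genes not being independent). For sh4 these lists differed by 0.87 (2.32 and 1.45, permutation p = 0.0275), under the limit of 1. Choroid plexus and neural crest genes, compared after that was seen, differed by 2.78 (2.48, 22 genes, and -0.30, 19 genes, permutation p = 0.00028). These lists did not rise alike, but the p-values partly restate how the lists were picked, so a lower share of neural cells stays open. Organoid sets that differ for reasons other than KDM2A cannot be told apart from an effect of the hairpins, which stays open too, since each label is 1 set and sh1 against sh4 gave 0.965 times the calls of sh1 against NC and 0.544 times those of sh4 against NC (3841, 3980 and 7057), or 0.777 and 0.476 times without NC 2 and sh4 1.

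In the NPCs labelled sh1 and sh4 MYC, KLF4 and POU5F1 were lower. The 15 tested genes of the pluripotency list besides POU5F1 had medians of 1.63 (sh1) and 2.38 (sh4), MYC and KLF4 being members of the immediate early list. Transcripts of these genes from 1 outside source in the NC libraries cannot be told apart from regulation in the cells. Within NC, KLF4 and POU5F1 followed MYC at 1.06 and 0.91 times the slope seen between groups, but 18.1% of 835 other genes called lower did so too. Over NC 1 to 5, MYC was at 4570, 3430, 4290, 3320 and 1920 CPM, KLF4 at 389, 288, 377, 293 and 146, and POU5F1 at 412, 342, 430, 366 and 227.

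Counts of calls were set against other splits of the same libraries. For NPC sh1 against sh4, where ZNF512 and IGF2 differed, 456 genes were called and at most 66 in the other splits. Only 1 of 100 splits, the real one, gave as many. The listed genes were taken as selected on sh1 values, which enter this contrast and favour the real labels. The splits therefore do not decide against a random division of these libraries. Nor do they exclude a chance difference between cultures. For organoid genes called the same way with both labels, such as GAD2 and ALB, the real count of 3226 was reached by 1 of 100 splits, and the highest other count was 3064. Of the 99 other splits 3 called any gene, each with 1 labelled set kept whole as the reference, in the split with 3064 the NC set. Only 100 of 840 possible splits were drawn, and others that keep the NC set whole could reach the real count. The count thus reflects whole sets that stand apart and not the division into sh1 and sh4. It does not exclude a chance difference between sets. For NPC sh1 against NC (1814, highest other 596), sh4 against NC (1784, 636), both hairpins (1293, 0) and the difference between systems (3440, 1757), 1 of 100 splits gave as many. This decides nothing, because the listed NPC genes were taken as selected on the difference between sh1 and NC. For sh4 against NC that selection acts through the NC libraries that both hairpins share. In the organoids sh1 against NC (3980), sh4 against NC (7057) and sh1 against sh4 (3841) had 10 splits each, too few for a share under 0.05, with 1 as large and a highest other of 0.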

How the results depend on the processing

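Leaving out abundant genes, leaving out NC 2 with sh4 1, scaling within each table, the alternatives for the KDM2A difference between systems, splits of the organoid NC libraries and leave-one-out ranges of overlaps and correlations were chosen after the result was seen. Of the alternatives to results that answer a comparison, 441 kept the call or count, 29 moved it, 7 weakened it, 2 strengthened it and 0 reversed it. For lists 1210 kept the result, 53 were stronger, 33 weaker and 1 reversed, and for named genes 12464, 65, 71 and 0. The reversed one was the organoid epithelium list, -0.56 with sh1 against NC alone, because sh4 with its opposite median was left out. With no fold minimum more genes were called by construction: 9796 (NPC sh1), 8686 (sh4), 8450 (both), 2723 (sh1 against sh4), 9324, 13495, 7706 and 10032 (organoids in the same order), 7871 for the difference between systems, and overlaps of 1454 (same sign) and 2051 (opposite). A stricter filter, with fewer genes tested, left 861 NPC genes with both hairpins. Pooled hairpins, which need no call with each, gave overlaps of 273 and 479. KDM2A in NPC sh4 reached -1.11 (-1.113) with library size alone, and in organoid sh4 -0.269 (adjusted p = 0.00844, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), short of the fold minimum. Lists passing numbered 1 (NPC) and 0 (organoids) with an estimated correlation, which allows for correlated genes, and 26 and 28 with fry, which asks a different question, against 10 and 17. With the NC libraries split the correlation was 0.847 (NPCs) and 0.777 (organoids).

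Without each library in turn, KDM2A ranged from -1.059 to -0.985 (NPC sh1), from -1.014 to -0.940 (NPC sh4) and from -1.090 to -0.984 (difference between systems), so that calls near the fold minimum of 1 came and went. The correlation of the hairpins ranged from 0.861 to 0.870 (NPCs) and from 0.810 to 0.853 (organoids), genes called with both hairpins from 1283 to 1429 and from 2813 to 3461. Without NC 2 and sh4 1 in the organoids 3304 genes were called with both labels. With a replicate block 1294 (NPC) and 3186 (organoids) genes were called with both hairpins, 1809, 1790 and 455 in the NPC comparisons, 3931, 6995 and 3763 in the organoid ones, and 3452 for the difference between systems. The replicate numbers were not taken as pairs, since correlations within a number exceeded 0.1 in 9 of 15 NPC pairs (-0.0995 to 0.393, all pairs of numbers 1 and 5 among them, with 6 of 15 libraries correlating best with their own number) and in 0 of 9 organoid pairs (-0.156 to 0.0352, 1 of 9). Whether libraries of a number shared a batch is not given in the sources used here. With 1 hairpin alone camera no longer passed for hindbrain, mesenchyme, neural crest and retina genes (sh1) and neuron genes (sh4) in the NPCs, nor for mitochondrial and Notch genes (sh1) in the organoids. Over both systems 7 list results became stronger with sh1 alone and 4 with sh4 alone. Totals of 15.9 to 18.9 M counts limit organoid folds of genes near 0 counts, such as NANOG and GSX2, and NPC totals cover listed genes alone.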

Other observations

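The list members described first and the values given for them were chosen after the result was seen; the tests of zinc finger genes were chosen before. Some neural regulators were called between sh1 and sh4 in the NPCs. PAX6, a transcription factor gene of the eye and dorsal forebrain, was higher with sh1 than with sh4 by 3.16 on the log2 scale (0.74 and -2.42 against NC), and BARHL2 by 2.58 (0.97 and -1.60). The clustered protocadherin genes PCDHGA3 (3.06, -0.78 and -3.84 against NC) and PCDHA6 (2.33, -0.71 and -3.04), whose counts are fractional, were higher with sh1 too. The Notch ligand gene DLL1 (-1.33, -0.79 and 0.54) and the neurotrophin receptor gene NTRK2 (-1.46, -2.30 and -0.84) were lower with sh1 than with sh4. KDM2A was lowered alike by the hairpins (-1.02 and -0.97), so its RNA level does not separate them.

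A hypothesis that zinc finger family genes are called lower with both hairpins more often than other genes was not met. In the NPCs 16 of 314 zinc finger genes were lower (5.1%) against 822 of 9546 other genes (8.61%), odds ratio 0.57 (95% interval 0.32 to 0.947, p = 0.03, two-sided Fisher's exact test). In the organoids it was 21 of 541 (3.88%) against 1282 of 19163 (6.69%), odds ratio 0.563 (0.344 to 0.874, p = 0.00821, two-sided Fisher's exact test). They were also called higher less often (odds ratio 0.395 and 0.0839, p = 0.0189 and 3.54e-18, two-sided Fisher's exact tests), and their median log2 changes were -0.31 and -0.26 against 0.07 and 0.02 for other genes. With RLE scaling the NPC odds ratio was 0.632 (p = 0.0659) and with library size alone 0.83 (p = 0.365, Fisher's exact tests). Genes of the family lie in clusters and are not independent.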
